A study of Sus scrofa with 2 samples.

How the data were processed

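Droplet single-cell RNA sequencing was run on pig thymocytes with the 10x Genomics Chromium 3′ kit, version 3.1 chemistry. Thymocytes came from 2 untreated pigs of mixed breed, 22 weeks old. Cells of both pigs were combined before each library, which gave 1 library of total thymocytes and 1 library of invariant natural killer T (iNKT) thymocytes taken from the same thymi. The iNKT cells were positively selected with magnetic beads, and live cells of both kinds were sorted by flow cytometry, per the labels' protocols.

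The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, per the file headers. Cell Ranger 3.1 and Seurat 3.1 are named per the submitters' processing notes, and the header of the matrices gives Cell Ranger 3.1.0. The genome build and the gene annotation were not given in the sources used here. The lowest total of a barcode was 500 UMIs in the total thymocyte library and 506 UMIs in the iNKT library.

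The matrices list 21301 genes by identifier. A symbol came from the deposited gene list for 14846 of them and from a table of gene names for another 687, and 5768 had none. After repeated symbols were set aside, 15523 symbols were usable. Each of the 2 libraries was filtered and clustered on its own. Cells were kept with at least 500 genes and at most 10% of UMIs from 13 mitochondrial genes. Doublets were scored with Scrublet at an expected rate of 0.08. Its automatic threshold called 0 of 8026 cells in the total thymocyte library and 1 of 11273 in the iNKT library, so doublet calling did not work and doublets remain in the data. An alternative removed the cells with the highest scores, as many as the expected rate.

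Counts per cell were scaled to 10000 and log-transformed. The 2000 most variable genes were taken after mitochondrial genes, 75 ribosomal protein genes, 11 antigen receptor genes and those members of the gene lists that were not cell type markers had been left out. Clustering used 30 principal components, 15 exact nearest neighbours and the Leiden method at resolution 1 (scanpy 1.11.5, igraph 0.11.9). The cell filters, the clustering settings, the marker genes, 16 gene lists, the comparisons, the rule for named genes and most alternatives were chosen before the data were examined. The rule that turns markers into names was set after the clusters had been seen, in 2 versions. In the version used, a cluster took the name of a class when at least 3 of its markers were detected and at least 3 were 2-fold or more above the median of the other clusters. Their median log2 fold had to reach 1, and no other class could hold more of the cluster's 10 leading genes. For this last condition CD4 single-positive, CD8 single-positive and naive mature T markers counted together as 1 group of classes, by its largest class, and so did B and plasma markers. Double-positive and single-positive names also needed their co-receptors above the other clusters, and regulatory T needed at least 50 CPM of FOXP3. A cluster with median UMIs far below those of its library needed a marker of its name among the leading genes. Names of a lineage other than T also needed CD3E at or below 0.25 of the other clusters. Clusters that met no such rule stayed unnamed. Cluster 6 of total thymocytes met it as naive mature T-like with 1 marker of that class and 2 cytotoxic markers among its 10 leading genes. Over its whole group of classes, single-positive markers included, it held 3 such markers. The text gives it by its number. Cluster 12 of total thymocytes and cluster 11 of the iNKT library met it as plasma-like through JCHAIN and MZB1, but HLA-DRA, SLA-DQB1 and CD79B were among their leading genes as well, so they are given by number too. The second comparison takes the clusters of total thymocytes named CD4 single-positive-like, CD8 single-positive-like or naive mature T-like, which was cluster 6 alone.

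For each comparison the UMIs were summed over cells and scaled to the library total as CPM. The ratio of CPM has an exact conditional binomial interval, a CPM value an exact Poisson interval and a share of cells an exact Clopper-Pearson interval, all at 95%. With 1 library per group no test across replicates could be run. Gene lists were summarised by the median log2 ratio of members with at least 100 UMIs over both groups, after adding 0.5 to each summed count, minus the median of all genes with that many. Each list median was placed among 10000 random lists of the same size matched on mean expression. The rule that sets apart lists outside the central 95% of these was made after the medians had been seen, in place of a set picked by hand. Members of a random list were drawn independently of each other. Real lists whose genes vary together can spread more widely, so lying outside this range is a description and not a test. Where a fold is given for a gene with 0 UMIs in one group, that group was set at a floor of 3 counts. The lower bound of the exact 95% interval, which lies below that fold, is given beside it.

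Named genes had a symbol and were not mitochondrial, ribosomal protein or antigen receptor genes. They needed at least 100 UMIs over both groups and at least 50 CPM in the higher group. The 12 highest and 12 lowest ratios were taken in the first comparison and the 10 highest and 10 lowest in the second, ranked by the interval bound nearest to 1. Lists add their 2 highest and 2 lowest members in each comparison, and across classes the 3 members with the largest ratio. ZBTB16, CD4, CD8A, CD8B, CD1D, GATA3, TBX21, IFNG, IL4 and IL17A were always to be named, and CD1D is not analysed here. Some of the genes that these rules select are given in full, others as counts or ranges, and a few are not reported here. Y-linked and X-linked genes, the globin gene HBB, CD79A, CD79B and ARHGEF1 were singled out after their values had been seen.

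Cycling cells were counted after each cell was thinned to 2000 UMIs, as cells with at least 10 UMIs of 83 cell cycle genes. Shallower cells were left out, 3252 in the total thymocyte library and 308 in the iNKT library. Alternatives covered both cell filters, doublets, TMM factors (edgeR 4.0.16), equal weight per cell, thinning, the minimum of UMIs, clusters left out, the Leiden resolution and seed, the number of variable genes and of components, and the settings of the cell cycle count.

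The ratio and its interval were tested on simulated counts. In the first comparison 200 of 10438 simulated genes were given a known fold, and all genes changed 3-fold or 4-fold were recovered as at least 2-fold in the right direction (100% at each size and direction). In the second comparison the simulation covered 9495 genes. There 94.3% of genes made 3-fold higher were recovered, and 100% of those made 4-fold higher, 3-fold lower or 4-fold lower. Intervals held the true fold in 95% of unchanged genes in the first comparison and in 95.4% in the second. The simulated counts were Poisson, as the intervals assume, without variation between cells, animals or libraries. They check the calculation and not its use on real libraries. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.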

Results

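The deposited data hold 1 library of total thymocytes and 1 library of iNKT thymocytes, each made from pooled cells of the same 2 pigs. iNKT cells are T cells with a semi-invariant receptor for lipid antigens, and they develop in the thymus. The total thymocyte library held 9112 barcodes with 29723207 UMIs, a median of 2148 UMIs and 1017 genes per barcode. The iNKT library held 12097 barcodes with 54457966 UMIs, a median of 4074 UMIs and 1480 genes. After filtering, 8026 total thymocytes (88.1%) and 11272 iNKT thymocytes (93.2%) remained, with medians of 2414.5 and 4210 UMIs. There was no replicate library of either kind, so the differences below have no replicate check, and every interval covers counting error only. Bead selection was described for the iNKT cells alone. Any effect of it on transcripts cannot be told apart from cell kind in either comparison.

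The first comparison asked how the transcripts of iNKT thymocytes differ from those of the whole thymus. ZBTB16, which encodes the transcription factor PLZF of innate-like T cells, stood at 224.5 CPM in the iNKT library and 0.385 CPM in total thymocytes, a ratio of 583 (95% interval 326 to 1168). Transcripts of thymocytes that rearrange their receptors were close to absent from the iNKT library. RAG1, a subunit of the recombinase, was 1542-fold lower (838 to 3217), and PTCRA, the pre-T cell receptor alpha chain, was 1490-fold lower (852.5 to 2884). Of 47 genes of the G2 and M phases, 45 were at least 2-fold lower in the iNKT library, while 15 of 18 interferon-stimulated genes and 8 of 12 cytokines and chemokines were at least 2-fold higher.

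Among the 12 genes with the highest ratios, TNFRSF4, the costimulatory receptor OX40, stood at 1258 CPM in the iNKT library against 23.1 CPM, a ratio of 54.5 (50.5 to 59.0). FAM111A had a ratio of 109 (77.3 to 160), and DDC, which encodes aromatic amino acid decarboxylase, a ratio of 98.1 (65.8 to 153). FOSB, an immediate early transcription factor, and the tetraspanin CD9 had ratios of 58.2 and 46.1. HPGDS, the prostaglandin D synthase of blood cells, and IL6R, the interleukin 6 receptor, had ratios of 37.6 and 26.6. PDE7B, NDST3, MCUB and FAM110D, with ratios of 30.6 to 37.5, complete these genes.

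The 12 genes with the lowest ratios included both chains of the recombinase, with RAG2 at 155.6 CPM in total thymocytes and 4 UMIs in the iNKT library. DNTT, the polymerase that adds nucleotides at receptor junctions, had 3 UMIs in the iNKT library against 6031, a ratio of 0.000267 (5.5e-05 to 0.00078). CD1E, a lipid-binding protein of the CD1 family, had 1 UMI against 5395. FABP6, an intracellular bile acid binding protein, was 3535-fold lower (2177 to 6186). EPCAM, ARPP21, HHIP and ARSG belonged to this group as well.

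The co-receptor genes differed strongly between the libraries. CD4 stood at 1.07 CPM in the iNKT library and 144 CPM in total thymocytes, 134-fold lower (103 to 177.5). CD8B was 1139-fold lower (759 to 1798) and CD8A 16.0-fold lower (14.9 to 17.2). GATA3, the transcription factor of type 2 responses, had a ratio of 0.576 (0.559 to 0.594), and TBX21, which encodes T-bet, a ratio of 0.0999 (0.0636 to 0.151). IL4 had 1349 UMIs in the iNKT library and 1 UMI in total thymocytes, a ratio of 723 (130 to 28600). IFNG had 0 and 1 UMIs and IL17A had 0 UMIs in both libraries, so no fold is given for either.

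A UMI of ZBTB16 was found in 55.3% of iNKT cells (54.4 to 56.2) and in 9 of 8026 total thymocytes (0.112%, 0.0513 to 0.213). With each cell thinned to 2000 UMIs the shares were 32.7% (31.9 to 33.6) and 0.0628% (0.013 to 0.184).

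Of the 16 gene lists, 7 lay above and 4 below the central 95% of matched random lists. Values are relative to the median of all genes, which lay at −0.24 and would lie at 0.07 with TMM factors. Interferon-stimulated genes had the highest median log2 ratio, 2.14, with none of its 18 measured members 2-fold lower, and with members such as RSAD2 at a ratio of 12.9 (10.7 to 15.8) and MX2 at 12.4 (10.6 to 14.7). Cytokines and chemokines had a median of 1.86, with 2 of 12 members at least 2-fold lower. CD40LG, the ligand of CD40, was at a ratio of 15.2 (14.2 to 16.4), whereas the chemokines CCL5 and XCL1 had ratios of 0.139 and 0.158. Chemokine receptors and migration genes had a median of 1.22, with 9 of 19 members at least 2-fold higher and 5 lower. These counts were 10 and 3 with TMM factors, 7 and 6 with equal weight per cell, where the median was 0.58, and 6 and 6 without cycling-like clusters. The list was led by KLF2, a transcription factor of thymic egress, at 9.22 (8.79 to 9.67) and CCR7 at 7.36 (7.07 to 7.67). CXCR4 and CXCR3 were lower at 0.175 and 0.172.

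Immediate early and heat shock genes had a median of 1.04, with 7 of 17 members at least 2-fold higher and 1 lower (9 and 0 with TMM factors) and FOS at a ratio of 9.63 (9.16 to 10.1). For this list too, the bead selection of iNKT cells cannot be told apart from cell kind. Cytokine receptors had a median of 0.88, with 7 of 18 members at least 2-fold higher and 0 lower (7 and 1 with equal weight per cell) and IL6ST, the shared signalling chain gp130, at 13.4 (12.4 to 14.5). T cell receptor signalling and costimulation genes had a median of 0.87, with 11 of 27 members at least 2-fold higher and 3 lower and CD5, a receptor whose level follows receptor signal strength, at 7.0 (6.74 to 7.26). Glycolysis genes had a median of 0.84, with 3 of 15 members at least 2-fold higher (6 with TMM factors) and the lactate transporter SLC16A3 at 9.24 (8.13 to 10.5).

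Lower lists were led by genes of the G2 and M phases, at a median of −3.40, among them CDC20 at a ratio of 0.0305 (0.0265 to 0.0348). Receptor recombination genes had a median of −1.92 with 8 of 11 members at least 2-fold lower, and S phase genes a median of −1.64, with 30 of 34 S phase members at least 2-fold lower and UHRF1 at 0.0245 (0.0221 to 0.0272). Without the clusters named cycling-like, which leaves in dividing cells of other clusters, such as cluster 7 with PCLAF and TK1 among its leading genes, the S phase median was −0.91 and the G2 and M phase median −1.44, with 24 of 33 members lower. Equal weight per cell gave an S phase median of −0.87. Cytotoxic effectors had a median of −0.53, with 4 of 14 members at least 2-fold higher and 6 lower, although their summed level was higher in the iNKT library, at 2291 CPM against 1624 CPM. Their median was −0.98 with equal weight per cell. CST7 stood at a ratio of 6.19 (5.80 to 6.62), while GNLY, which encodes granulysin, had 0 UMIs in the iNKT library and 165 in total thymocytes.

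The other 5 lists lay within the range of random lists. Apoptosis genes had a median of 0.30, MHC class II genes 0.14, oxidative phosphorylation genes 0.13, and T cell transcription factors and receptors of the NK and SLAM families each −0.12. Transcription factors turned to 0.24 with at most 5% mitochondrial UMIs, and MHC class II genes to −0.11 with thinning and −0.73 with a minimum of 20 UMIs. Receptors of the NK and SLAM families stood at −1.02 with a minimum of 20 UMIs, where 8 of 14 members were at least 2-fold lower, at −0.50 with equal weight per cell and at −0.51 without cycling-like clusters, and MHC class II genes stood at 0.52 without clusters of other lineages and 0.33 with equal weight per cell. Among these, ZBTB7B, the transcription factor of the CD4 lineage, was at a ratio of 13.2 (11.1 to 16.0) and BCL2L1, which protects double-positive thymocytes from death, at 0.110. SLAMF7 stood at 0.00664 (0.00456 to 0.00935).

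**Figure D1:**
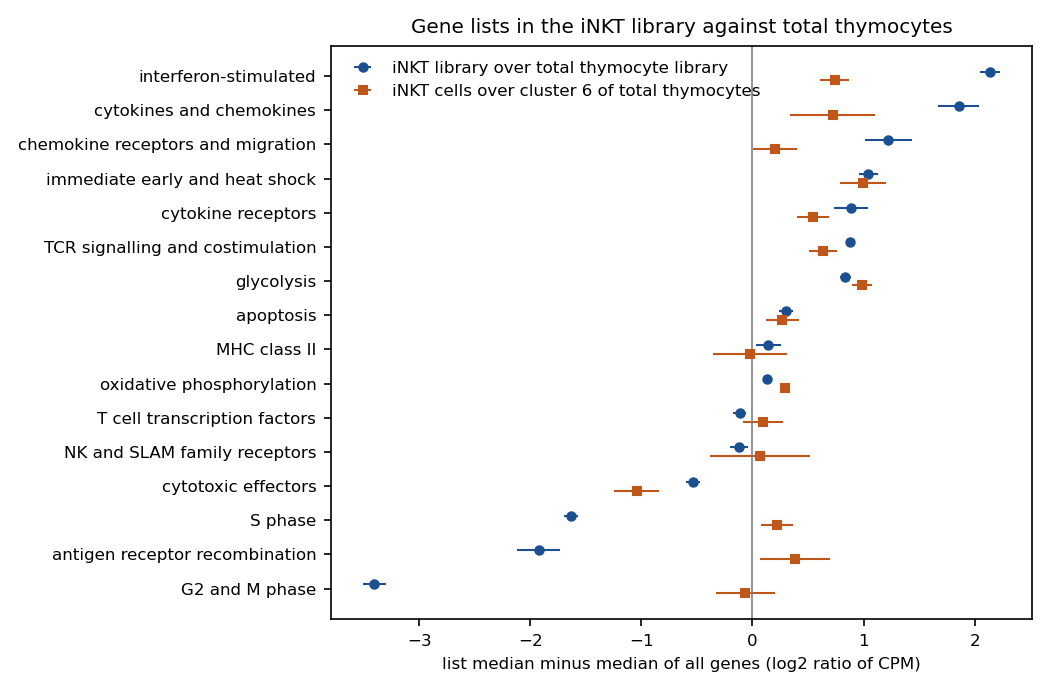
Median log2 ratio of CPM for each of the 16 gene lists, minus the median of all genes, in the iNKT library over the total thymocyte library (circles) and in iNKT cells over cluster 6 of total thymocytes (squares); bars show counting error only. Interferon-stimulated genes lie highest, at 2.14, and G2 and M phase genes lowest, at −3.40, in the first comparison.

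The second comparison set iNKT cells against mature thymocytes, to compare cells closer in stage. It used 11115 iNKT cells outside the cycling-like cluster and cluster 11, with 51822717 UMIs, and the 849 cells of cluster 6 of the total thymocyte library, with 2888460 UMIs. The iNKT side kept the 1024 cells of an unnamed iNKT cluster with PCLAF, CDT1, MCM5 and TK1 among its leading genes. Cluster 6 of total thymocytes was named naive mature T-like, but just 1 marker of its own name, CCR7, was among its 10 leading genes. These also held GZMH, XCL1 and GZMM, the CD4 single-positive marker CD40LG and the CD8 single-positive marker CRTAM. Cluster 6 is therefore compared by its number. ZBTB16 stood at 224.4 CPM against 0.692 CPM, a ratio of 324 (89.7 to 2677). S100A4, a calcium-binding protein of effector and memory T cells, had a ratio of 354 (138 to 1299). UMIs of S100A4 were found in 4826 of the 11115 iNKT cells. S100A4 was also a leading gene of gamma-delta T-like cluster 4 and interferon-response-like cluster 13 of total thymocytes. At least 2-fold higher in iNKT cells were 8 of 17 immediate early and heat shock genes, 8 of 18 interferon-stimulated genes and 5 of 15 glycolysis genes, with none of these lists' members 2-fold lower, while 7 of 12 cytotoxic effectors were at least 2-fold lower. The iNKT cells included the 984 cells of interferon-response-like cluster 7, whereas the comparator left out the 132 cells of interferon-response-like cluster 13 of total thymocytes, which favours higher interferon-stimulated genes.

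Further genes with high ratios were S100A6 at 104 (55.0 to 228), S100A11 at 60.7 (35.5 to 114), CD9 at 156 (43.1 to 1287) and FOSB at 73.9 (25.3 to 358). UCP2, a mitochondrial carrier protein, had a ratio of 18.5 (14.5 to 24.1) and DDC of 40.1 (18.4 to 109). FAM111A and EPHB1 had 0 UMIs in cluster 6 and were at least 120-fold and at least 48.3-fold higher in iNKT cells. CD8B was 678-fold lower in iNKT cells (449 to 1075), CD4 82.5-fold (61.7 to 112) and CD8A 14.5-fold (13.1 to 16.1). GZMM and GZMH, which encode granzymes, were 185-fold (121 to 294) and 61-fold (55.2 to 67.5) lower. FABP6, MYOM1, ARPP21, MCOLN2, BEX3 and ANGPT2 were the other genes with low ratios, 19.1-fold to 219-fold lower. FABP6 and MYOM1 were also leading genes of double-positive-like cluster 3, and ARPP21 is a double-positive marker. FABP6 stood at 67.5 CPM in cluster 6 and 1062 CPM in total thymocytes, and ARPP21 at 56.8 and 602 CPM. Of 5 measured double-positive markers, 4 were at least 2-fold lower in iNKT cells and 0 higher, at a median of −2.28. Whether transcripts of double-positive cells in cluster 6 add to these ratios and to those of the co-receptors was not tested.

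GATA3 did not differ detectably when scaled to the library total, at a ratio of 1.09 (0.994 to 1.21). TMM factors of 0.915 for iNKT cells and 1.093 for cluster 6 would place the whole interval above 1. TBX21 had 3 UMIs in cluster 6, and its ratio of 0.483 (0.148 to 2.49) was not resolved at this depth. IL4 had 1333 UMIs in the iNKT cells and 1 UMI in cluster 6, a ratio of 74.3 (13.3 to 2937). IFNG and IL17A had 0 UMIs on both sides.

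In this comparison 6 of the 16 lists lay above and 1 below the central 95% of random lists, relative to a median of all genes of −0.15 that TMM factors moved to 0.10. Immediate early and heat shock genes had a median of 0.99, with ATF3 at a ratio of 9.78 (3.80 to 36.0). Glycolysis genes also had a median of 0.99, with SLC16A3 at 3.78 (2.94 to 4.94), and 9 instead of 5 of 15 members were at least 2-fold higher with TMM factors. Interferon-stimulated genes had a median of 0.74, led by RSAD2 at 11.5 (6.73 to 21.7), and IFI44L was lower at 0.696 (0.640 to 0.758). This result depended on the cells taken, since a minimum of 200 genes, at most 5% mitochondrial UMIs and removal of the highest doublet scores each left 4 of 18 members at least 2-fold higher and 1 lower, with medians of 0.42, 0.37 and 0.34. With the 984 cells left out of the iNKT side, or the 132 cells added to the comparator, 6 of 18 members were at least 2-fold higher and 1 lower, with medians of 0.41 and 0.43. With 15 components the median was 1.20. Cytokines and chemokines had a median of 0.72, with 5 of 12 members at least 2-fold higher and 2 lower, and medians of 0.39 with a minimum of 200 genes and 1.18 with 15 components. T cell receptor signalling and costimulation genes had a median of 0.63, with 7 of 25 members at least 2-fold higher and 4 lower (10 and 2 with TMM factors), and their summed level was 6199 CPM in iNKT cells against 6711 CPM. Cytokine receptors had a median of 0.55, with 4 of 18 members at least 2-fold higher and 2 lower, and 3 and 4 with a median of 0.25 without the highest doublet scores. NR4A2, an early response gene of receptor signalling, stood at 6.70 (4.38 to 10.9) and TGFBR2 at 0.222 (0.190 to 0.261).

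Cytotoxic effectors had a median of −1.04, and of −0.67 with 15 components, where 4 instead of 7 of 12 members were at least 2-fold lower, although CST7 and SRGN stood at ratios of 8.85 (7.0 to 11.4) and 5.11 (4.75 to 5.51). The remaining 9 lists lay within the range of random lists. Their medians were 0.38 for receptor recombination, 0.29 for oxidative phosphorylation, 0.27 for apoptosis, 0.22 for S phase, 0.20 for chemokine receptors and migration, 0.10 for transcription factors, 0.07 for receptors of the NK and SLAM families, −0.03 for MHC class II and −0.06 for G2 and M phase genes. The sign of several was not fixed. Recombination genes turned to −0.65 with a minimum of 20 UMIs, where 5 of 11 members were at least 2-fold lower, transcription factors took the other sign in 10 of 15 alternatives and MHC class II genes in 6, and S phase, chemokine receptor and G2 and M phase genes did so in 2, 1 and 1. Among transcription factors MAF, a regulator of IL4, had 1799 UMIs against 3, a ratio of 33.4 (11.4 to 162), and TOX2 had a ratio of 0.205 (0.185 to 0.228).

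Cluster 6 held cells with either co-receptor. After thinning, 10.9% of its 790 cells (8.80 to 13.3) had a CD4 UMI and no CD8A or CD8B UMI, 42.9% (39.4 to 46.4) had the reverse, 3.67% had both and 42.5% neither. In gamma-delta T-like cells, which mostly lack both co-receptors, the shares were 0.557%, 8.72%, 1.11% and 89.6%, at median depths of 4582 UMIs there and 3209 UMIs in cluster 6. In double-positive-like cells, also after thinning, 41.7% had a CD8A or CD8B UMI and no CD4 UMI, and 54.2% had both. A missing UMI therefore does not show that a cell lacks that co-receptor.

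Total thymocytes formed 15 clusters, of which 12 met the naming rule, among them clusters 6 and 12, which are given by number. Double-positive-like cells made up 34.5% of the library (33.5 to 35.6), post-selection-like cells 13.9% (13.2 to 14.7), cycling-like cells 12.2% (11.5 to 12.9) and cluster 6 held 10.6% (9.91 to 11.3). Gamma-delta T-like cells made up 6.79% (6.25 to 7.36), interferon-response-like cells 1.64% (1.38 to 1.95), cytotoxic T or NK-like cells 1.16% (0.936 to 1.42) and cluster 12, with HLA-DRA, SLA-DQB1 and CD79B beside the plasma cell genes JCHAIN and MZB1 among its leading genes, 0.523% (0.377 to 0.707). IRF8, used here as a plasmacytoid dendritic marker, was also a leading gene of cluster 12. The 3 unnamed clusters held 18.6% of cells (17.8 to 19.5). Most of these were in cluster 1, with 13.3% of cells and DNTT, PTCRA and RAG1 among its leading genes. In it 6 of 10 detected double-positive markers were at least 2-fold higher, but it did not meet that name. The shares of the named classes moved with the clustering and filter settings, over 22.6% to 36.2% for double-positive-like, 0% to 14.6% for post-selection-like, 7.33% to 16.9% for cycling-like, 3.16% to 7.95% for gamma-delta T-like, 0% to 1.87% for interferon-response-like and 1.13% to 9.02% for cytotoxic T or NK-like cells. The name that cluster 6 met, naive mature T-like, took 0% to 15.1%, with 0% at resolutions 0.5 and 1.5, with 4000 variable genes and under the first naming rule.

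iNKT thymocytes formed 12 clusters, of which 5 were named, and 87% of cells (86.4 to 87.7) stayed in unnamed clusters. Interferon-response-like cells made up 8.73% (8.21 to 9.27), cytotoxic T or NK-like cells 2.83% (2.53 to 3.15), cycling-like cells 1.28% (1.08 to 1.5) and cluster 11, which shared the leading genes HLA-DRA, SLA-DQB1, CD79B, JCHAIN and MZB1 with cluster 12 of total thymocytes, 0.115% (0.0614 to 0.197). Over the alternatives these shares ranged from 5.41% to 9.46%, 0.964% to 3.01%, 0.798% to 7.8% and 0% to 0.123%. The cytotoxic share was 0.964% to 1.22% in 8 of 10 alternatives, and the cycling share was 1.92% or more in 8 of 10, so neither main value is typical. Unnamed cluster 6, with 9.08% of cells, had PCLAF, CDT1, MCM5 and TK1 among its leading genes and is not in the cycling share. The bead selection and the sort set which cells could enter this library. UMIs of the Y-linked genes EIF1AY, KDM5D and ZFY together ranged from 2.82 CPM in cluster 5 to 116 CPM in cluster 0.

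**Figure D2:**
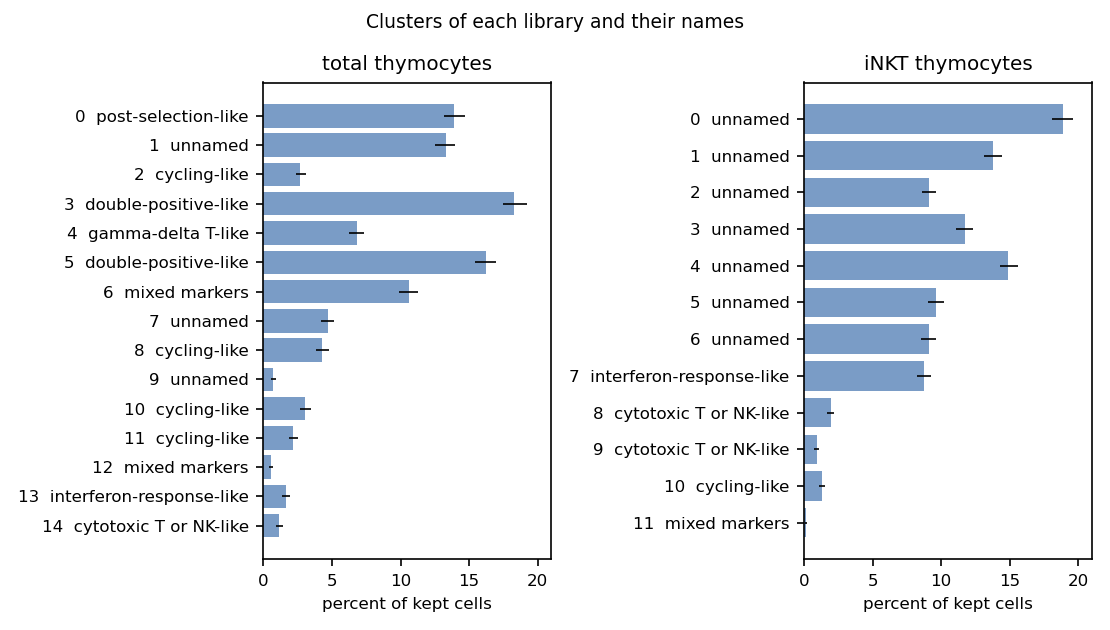
Share of kept cells in each cluster of total thymocytes (left) and iNKT thymocytes (right), in percent, with exact 95% intervals as bars and the name of each cluster beside its number; clusters 6 and 12 of total thymocytes and cluster 11 of iNKT thymocytes are marked as having mixed markers. The largest clusters hold 18.3% of total thymocytes and 18.9% of iNKT thymocytes.

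**Figure D3:**
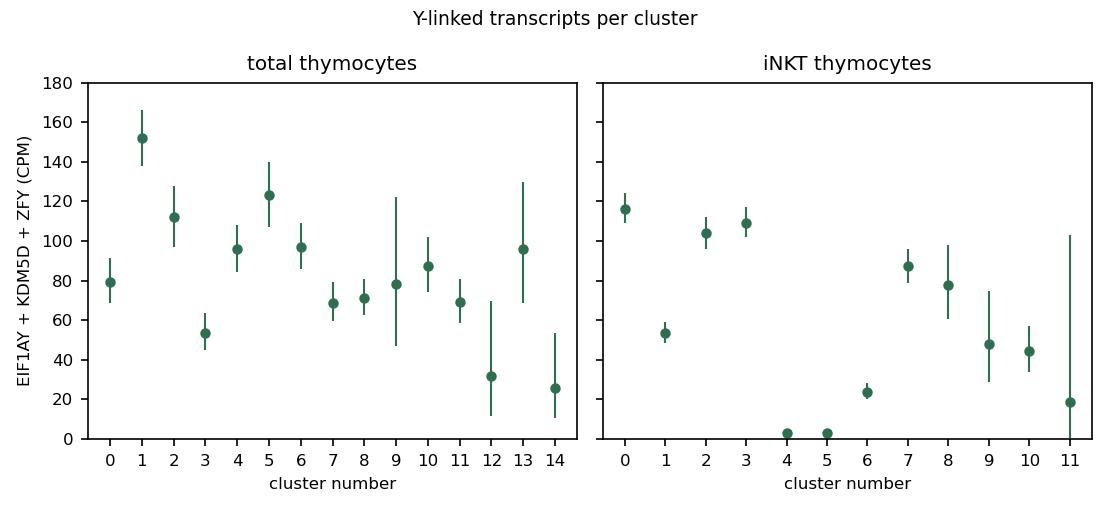
Summed CPM of the Y-linked genes EIF1AY, KDM5D and ZFY in each cluster of total thymocytes (left) and iNKT thymocytes (right), with exact 95% Poisson intervals as bars. iNKT clusters 4 and 5 lie at 2.98 and 2.82 CPM, below every cluster of total thymocytes.

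Genes of the lists that had not been used for clustering differed across the iNKT clusters. Markers related to some of them were not left out, such as ISG15 and RSAD2, which lead cluster 7, and CD69 and CTLA4, which lead cluster 1. Levels across clusters, in either library, are therefore not independent of the clustering. Unnamed cluster 1 held the highest levels of CCL4, a chemokine of activated T cells, at 239.5 CPM (229 to 251) against 5.75 CPM in cluster 3. The same cluster was highest in TNFSF11, which encodes RANKL, at 185 CPM against 25.0 CPM in cluster 0, and in EGR2, a transcription factor induced by receptor signalling, at 77.7 CPM against 7.89 CPM in cluster 6. It was also highest in IL4, at 60.7 CPM (55.3 to 66.5) against 11.5 CPM (6.56 to 18.6) in cycling-like cells, and in NFATC1 and BCL2A1, which lies downstream of NF-kB, at 81.4 and 67.3 CPM. CXCR3, a receptor for interferon-induced chemokines, was at 66.4 CPM (53.3 to 81.9) in cytotoxic T or NK-like cells and had 0 UMIs in cluster 0, at least 167-fold lower. FOSB was highest in cluster 0, at 136 CPM against 29.4 CPM in cycling-like cells. HERC5 and OAS2, which are induced by interferon, were highest in interferon-response-like cells at 97.9 and 189 CPM.

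Across total thymocytes, CCL4 stood at 817.5 CPM (713 to 933) in cytotoxic T or NK-like cells and had 0 UMIs in cluster 7, at least 791-fold lower. IL2RB, a chain of the interleukin 2 and 15 receptors, was at 370 CPM in the same cells and had 2 UMIs in double-positive-like cells. CCR4 and NR4A3 were highest in unnamed cluster 9, at 450 CPM (369 to 543) and 433 CPM (354 to 524.5). DCLRE1C, the nuclease that opens receptor gene hairpins, and LIG4, the ligase that joins the ends, were highest in double-positive-like cells at 297 and 48.7 CPM. HSPA6, an inducible heat shock protein, was highest in post-selection-like cells at 1201 CPM (1157 to 1246).

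Cycling cells were more frequent among total thymocytes. At 2000 UMIs per cell, 30% of 4774 total thymocytes (28.7 to 31.3) and 2.52% of 10964 iNKT thymocytes (2.23 to 2.83) held at least 10 UMIs of cell cycle genes. The number of cells within 2 UMIs of that minimum was 338 and 272, so the share in the iNKT library depends on where the minimum lies. Thinning left out 3252 total and 308 iNKT thymocytes. It kept 520 of 2772 double-positive-like cells, while the cycling-like clusters of total thymocytes had median depths of 6409 UMIs or more, so the 30% belongs to deeper cells richer in cycling cells. Thinned to 1000 UMIs with a minimum of 5, the shares were 25.4% of 7264 total and 4.24% of 11237 iNKT thymocytes. Unthinned, they were 25.4% and 20.1%, at unequal depth. Clusters named cycling-like held 12.2% and 1.28% of kept cells. Free RNA from dividing cells can add UMIs to cells that do not divide, and its part in these shares stayed open.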

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

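The test of the globin pattern was chosen only after the result was seen.

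Barcodes that the cell filters left out of the total thymocyte library held 56271 UMIs of HBB, the beta-globin gene, 12 of them with at least 100 such UMIs, and those left out of the iNKT library held 1 HBB UMI. Genes without a symbol, which entered no named result, held 11.5% of the UMIs of kept total thymocytes and 12% of the UMIs of kept iNKT thymocytes.

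Kept cells of the total thymocyte library held 18008 HBB UMIs, and 17485 of them lay in unnamed cluster 7, whose leading gene was HBB. Erythroid cells within the cluster are a candidate source, and 99.9% of its HBB UMIs lay in 2 cells with no CD3E UMI, which held 9609 and 7865 HBB UMIs. The other cells of the cluster held 11 HBB UMIs, and without those 2 cells the cluster took the name cycling-like. Earlier tests of free RNA and of doublets as the source had too few globin-rich cells to decide anything and were replaced by this one. No biological explanation was tested, since no group of the design bears on it.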

How the results depend on the processing

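The removal of the highest doublet scores, the comparison without the globin-rich cluster 7, the comparison without cytotoxic-like iNKT cells, the first naming rule and the naming without 2 globin-rich cells were chosen only after the data were seen, as were, for the second comparison, 4000 variable genes, 15 components, seed 1, iNKT cells without interferon-response-like cells and a comparator with such cells added. No paired analysis was possible because each group has 1 library, so no result comes from a test. A value counts as moved when it leaves its counting interval, and the cause of the moves was not tested except where the setting itself gives it. In the first comparison 124 of 176 list medians under alternatives stayed within counting error, 49 moved in size and 3 changed sign by more than counting error, while 4 in all had the other sign. In the second 197 of 240 stayed, 42 moved and 1 changed sign by more than counting error, while 22 in all had the other sign, 10 of them for transcription factors. The values that stayed include those with TMM factors. These factors add the same amount to every log2 ratio, so they cannot move a median taken relative to all genes. In the first comparison, keeping called doublets added 1 cell to the iNKT library and 0 to total thymocytes, so its medians could hardly move. Medians of the lists outside the range of random lists kept their sign under every alternative run, which these settings did not test.

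In the first comparison, with at most 5% mitochondrial UMIs, the medians were 1.5 for cytokines, 1.01 for receptor signalling, 0.76 for glycolysis, −1.80 for S phase, −3.85 for G2 and M and 0.72 for immediate early and heat shock, and that of transcription factors changed sign to 0.24. With equal weight per cell they were −0.98 for cytotoxic effectors, 0.58 for chemokine receptors, 0.65 for receptor signalling, 1.13 for glycolysis, −0.87 for S phase and −2.75 for G2 and M. Thinning to 2000 UMIs gave −0.42 for cytotoxic effectors, −1.44 for S phase, −3.60 for G2 and M and 1.82 for interferon genes, and turned MHC class II to −0.11. A minimum of 20 UMIs gave 0.70 for cytokine receptors and 0.97 for receptor signalling, and turned MHC class II, with few members, to −0.73. Without cycling-like clusters, which leaves dividing cells of other clusters in, the medians were −0.91 for S phase and −1.44 for G2 and M. The same setting gave 1.55 for cytokines, −0.89 for cytotoxic effectors, 0.93 for chemokine receptors, 0.68 for receptor signalling, 0.97 for glycolysis, 1.18 for immediate early and heat shock and 1.79 for interferon genes. Without cluster 7 they were −0.62 for cytotoxic effectors, 0.81 for receptor signalling, −1.43 for S phase and 2.04 for interferon genes. Removal of the highest doublet scores gave 1.14 for cytokine receptors.

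In the second comparison a minimum of 200 genes gave 0.30 for cytokine receptors and 0.42 for interferon genes, and at most 5% mitochondrial UMIs gave 0.37 for interferon genes. Removal of the highest doublet scores gave −0.73 for cytotoxic effectors, 0.25 for cytokine receptors, 0.85 for glycolysis and 0.34 for interferon genes. Leiden resolution 0.5 gave 0.34, 0.87 and 0.48 for cytokine receptors, glycolysis and interferon genes, with a comparator of 959 cells in 1 cluster that was named CD4 single-positive-like there. With 4000 variable genes the medians were −0.82 for cytotoxic effectors, 0.32 for cytokine receptors, 0.50 for receptor signalling and 0.44 for interferon genes, and with 15 components 1.18 for cytokines, −0.67 for cytotoxic effectors and 1.20 for interferon genes, over comparators of 906 and 1497 cells. Seed 1 moved none of the lists outside the range of random lists. iNKT cells without interferon-response-like cells gave 0.41 for interferon genes, and interferon-response-like cells added to the comparator gave 0.43 for interferon genes, 0.37 for cytokine receptors and 0.88 for glycolysis. A minimum of 20 UMIs turned recombination genes to −0.65, since more members at low counts enter. At Leiden resolution 1.5 no cluster took any of the 3 names of the comparator, and in the main clustering none was CD4 or CD8 single-positive-like, so these alternatives were not run.

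Counts of list members at least 2-fold apart moved as well. In the first comparison chemokine receptors and migration genes had 9 of 19 members higher and 5 lower, against 10 and 3 with TMM factors, 7 and 6 with equal weight per cell and 6 and 6 without cycling-like clusters. Glycolysis had 3 of 15 members higher, against 6 with TMM factors and 5 both with equal weight per cell and without cycling-like clusters. Immediate early and heat shock genes had 7 of 17 higher and 1 lower, against 9 and 0 with TMM factors, and 7 and 0 with at most 5% mitochondrial UMIs or thinning. Cytokine receptors had 7 of 18 higher and 0 lower, against 7 and 1 with equal weight per cell and 7 and 2 of 21 with a minimum of 20 UMIs. Without cycling-like clusters 24 of 33 G2 and M members were lower, against 45 of 47.

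In the second comparison interferon genes had 8 of 18 members higher and 0 lower. A minimum of 200 genes, at most 5% mitochondrial UMIs and removal of the highest doublet scores each gave 4 and 1, resolution 0.5 and 4000 variable genes each gave 5 and 1, and 6 and 1 remained both without interferon-response-like iNKT cells and with such cells added to the comparator. Cytotoxic effectors had 3 of 12 higher and 7 lower, against 3 and 4 with 15 components. Receptor signalling had 7 of 25 members higher and 4 lower, against 10 and 2 with TMM factors, 8 and 2 with at most 5% mitochondrial UMIs, and 6 and 2 each with a minimum of 200 genes, at resolution 0.5 and without the highest doublet scores. Glycolysis had 5 of 15 higher, against 9 with TMM factors and 3 of 14 with at most 5% mitochondrial UMIs. Cytokine receptors had 4 of 18 higher and 2 lower, against 3 and 3 with a minimum of 200 genes, at resolution 0.5, with 4000 variable genes and with interferon-response-like cells added to the comparator, 2 and 3 of 17 with at most 5% mitochondrial UMIs, and 3 and 4 without the highest doublet scores. Cytokines and chemokines had 5 of 12 higher and 2 lower, against 4 and 3 with a minimum of 200 genes.

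Shares of cycling cells moved to 25.4% of total and 4.24% of iNKT thymocytes with thinning to 1000 UMIs and a minimum of 5, and to 22.1% and 0.939% with a minimum of 20. At most 5% mitochondrial UMIs gave 2.13% in the iNKT library. The other 7 of 12 values stayed within counting error. Among them is the share of total thymocytes with called doublets kept, which could not move because 0 doublets were called there.

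Of 128 class shares under alternatives 68 stayed and 60 moved, so the named classes depend on the clustering. Keeping called doublets could not move the shares of total thymocytes, where 0 were called. In total thymocytes a minimum of 200 genes gave 15.4% cycling, 7.8% gamma-delta, 0% interferon-response and 4.54% post-selection. At most 5% mitochondrial UMIs gave 11.4% cycling, 1.67% cytotoxic, 22.6% double-positive, 6.25% gamma-delta, 0% interferon-response and 15.1% naive mature. Resolution 0.5 gave 15.4% cycling, 7.95% gamma-delta, 0% interferon-response and 0% naive mature. Resolution 1.5 gave 9.02% cytotoxic, 36.2% double-positive, 3.71% gamma-delta, and 0% interferon-response, 0% naive mature and 0% post-selection. With 4000 variable genes, interferon-response and naive mature were each 0%, and with 15 components double-positive was 36.2% and post-selection 0%. Seed 1 gave 12.9% post-selection. Removal of the highest doublet scores gave 15.3% cycling, 36.1% double-positive, 3.16% gamma-delta, 0% interferon-response and 12.2% naive mature. The first naming rule gave 7.33% cycling and 0% naive mature, and naming without 2 globin-rich cells 16.9% cycling.

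In the iNKT library the cycling, cytotoxic and interferon-response shares were 2.18%, 1.18% and 7.87% with a minimum of 200 genes and 0.798%, 0.964% and 9.46% with at most 5% mitochondrial UMIs, where plasma was 0%. With 15 components they were 2.11%, 1.12% and 7.35%, with plasma at 0%. They were 1.92%, 1.22% and 6.72% at resolution 1.5, 1.93%, 1.03% and 5.41% with 4000 variable genes, 2.06%, 1.2% and 8.06% with seed 1, and 1.98%, 1.22% and 8.05% without the highest doublet scores. Resolution 0.5 gave 7.8% cycling and 1.19% cytotoxic. Keeping the 1 called doublet gave 2.24% cycling and 8.2% interferon-response.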

Other observations

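The test of depth for the Y-linked genes and the test of free RNA for CD79A were chosen only after the result was seen.

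Markers of mature T cells, singled out here after their values were seen, gave a mixed picture. In the first comparison 5 of 7 measured markers of naive mature T cells were at least 2-fold higher in the iNKT library and 1 lower, at a list median of 2.67 relative to all genes, CD4 single-positive markers had 4 of 6 higher and 1 lower, at 2.57, and CD8 single-positive markers had 2 of 7 higher and 2 lower, at 0.17, within the range of random lists. Over cluster 6, naive mature T markers had 2 of 7 higher and 1 lower, at 0.22, and CD4 single-positive markers 2 of 6 higher and 1 lower, at 0.39, both within that range, while CD8 single-positive markers had 0 of 7 higher and 4 lower, at −1.67, below it. Over total thymocytes, IL7R, the interleukin 7 receptor, stood at a ratio of 5.87 (5.68 to 6.06) and S1PR1, the receptor that guides thymic exit, at 5.38 (4.75 to 6.11). The transcription factor TCF7 stood at 0.230 (0.225 to 0.235) in the same comparison. TNFRSF18, the costimulatory receptor GITR, stood at 21.1 (19.6 to 22.7) over total thymocytes and at 12 (10.1 to 14.3) over cluster 6.

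UMIs of the Y-linked genes EIF1AY, KDM5D and ZFY were nearly absent from iNKT clusters 4 and 5, at 2.98 CPM (1.80 to 4.66) and 2.82 CPM (1.54 to 4.74), against 77.7 to 116 CPM in clusters 0, 2, 3, 7 and 8, with clusters 1, 6, 9 and 10 between, at 53.7, 23.8, 47.8 and 44.5 CPM. Lower depth does not explain this, because at 2000 UMIs per cell 0.637% of cells in the low clusters (0.372 to 1.02) and 19.1% in the high clusters (18.1 to 20.2) held such a UMI. A pool of pigs of different sex may account for it: of the 100 autosomal genes that best separate the 2768 low from the 5670 high cells, 69% differed with the same sign between total thymocytes without and with a Y-linked UMI, compared within clusters, against a 95th percentile of 59% for random matched genes. The X-linked partners EIF1AX, DDX3X, KDM5C and KDM6A had a median log2 ratio of 0.17, low over high, at percentile 99.3 of random sets, with KDM5C alone below 1 at 0.940. The autosomal test cannot tell such a pool from Y-linked genes that vary with cell state, since genes varying with them would share signs in both libraries. Its random genes were drawn independently, although genes that separate clusters may vary together. Y-linked genes were not left out before the variable genes were taken, and KDM5D was a leading gene of iNKT cluster 3. The labels do not give the sex of the pigs, so a pool of different sex stays a hypothesis, and no biological explanation was tested. If that hypothesis holds, differences between iNKT clusters mix cell state with the animal.

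CD79A, a chain of the B cell receptor, was found at 118 to 263 CPM in every T cell cluster of total thymocytes and at 93.6 to 158 CPM in those of the iNKT library. Free RNA from B-lineage cells would carry CD79B along, yet CD79B stood to CD79A at 0.00774 over the T cell clusters of total thymocytes and 0.00547 over those of the iNKT library, against 0.647 in cluster 12 of total thymocytes and 0.911 in cluster 11 of the iNKT library, which hold B-lineage genes. Reads of a neighbouring gene counted for CD79A cannot be told apart from T cell expression. The highest ratio of CD79A to ARHGEF1 was 2.61 times the lowest over clusters of the iNKT library and 7.59 times over those of total thymocytes. All T cell clusters together held just 256 ARHGEF1 UMIs in the iNKT library and 254 in total thymocytes. Counting error in ARHGEF1 may therefore make up much of these spreads, so they cannot decide. RPS19, another neighbour, is not used here. No biological explanation was tested.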
